A study of Mus musculus with 12 samples.

How the data were processed

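The series holds 12 polyA RNA-seq libraries from MC3T3-E1 cells, a line of mouse bone-forming precursor cells from calvaria, in 4 groups of 3 libraries: untreated, TNFa, BMP4, and TNFa followed by BMP4. By the treatment protocol, cells were kept in 2.5% serum for 30 min, given TNFa at 10 ng/mL or not for 30 min, and then BMP4 at 10 ng/mL or not for 3 h. The sample characteristics give 3 h for each factor, so the exact length of the TNFa exposure is not settled by the labels. The labels also assign each library to a batch. Batch 1 holds replicate 1 of each group and batch 2 holds replicates 2 and 3, so each batch contains every group. The file header numbers the batches the other way round, with the same split of libraries, and the numbers of the labels are used here. The titles of the TNFa libraries carry the word p65, which the labels do not explain. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

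Sequencing was paired-end with 150 bp reads. The submitters' processing notes name Trim Galore, HISAT2 and HOMER with the mm10 genome build, and give no versions. Per the file headers, HOMER counted reads over exons for 1 transcript per gene, without normalization, and then tested differences between groups with batch as a factor. The single deposited table has 25124 entries, of which 7423 are listed at 0 in every library. Its 12 library columns are deposited as log2 values that are comparable between libraries and not adjusted for batch; the transformation is not named. The authors' log2 fold changes and the authors' p-value and adjusted p-value for each pair of groups are deposited in the same table, and the direct contrast of TNFa with BMP4 was not used here. Deposited differences between libraries are compressed at low levels: the slope of the differences on the authors' fold changes was 0.26 for genes with a mean log2 value from 4 to 6, 0.55 from 6 to 8, 0.79 from 8 to 10 and 0.92 above 10. Fold changes computed here for weakly expressed genes are therefore smaller than the authors'. Transcript positions are those of the file; 16625 of 24618 entries matched by symbol and chromosome had a start equal to that of the RefSeq annotation of the same build.

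A count model was planned before the data were examined, but the file holds no counts, so the log2 values were fitted with limma 3.58.1 in R 4.3.3. The model had the 4 groups and an additive batch term, moderated variances with a mean-variance trend, and 7 residual degrees of freedom. Genes with a mean log2 value of at least 4 were tested (11765 of the 17701 not at 0 throughout), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. The contrasts were the 5 pairs of groups that differ in TNFa, BMP4 or both against untreated, and the interaction, which is the TNFa effect with BMP4 minus the TNFa effect without it. Pairing of replicates beyond batch was checked and left out of the model, because the correlation of replicate differences between groups within batch 2 ran from 0.02 to 0.164. Fold changes are log2 with their standard error (SE), and levels are mean and SD over 3 libraries. All p-values are two-sided.

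Before the data were examined, 22 gene lists were fixed; 19 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera p-values were adjusted over the 114 combinations of list and contrast: 60 passed with the preset correlation and 13 with an estimated one. The lists for macrophages and other leukocytes, adipocytes, and endothelium and muscle had 2, 1 and 2 members above the minimum level and were not tested. List counts leave out members below the minimum, among them 10 of 18 chemokines, 10 of 16 cytokines and related regulators, and 7 of 18 osteoblast genes. The level is a mean over all libraries, so a gene can pass through the groups where it is high. Fry p-values were adjusted over the same combinations, and over the 2 responses (to TNFa and to BMP4), a step that was not planned and was added after the values were seen. Without it the test for change in either direction passed 0.05 for the TNFa response, and the joint-direction test did not. Alternatives for the responses were judged on unadjusted fry p-values. Genes were named by a rule fixed at the same time: per contrast, the 6 called genes with the largest rise and the 6 with the largest fall that moved the same way in both batches, the 2 members of each list with the largest absolute change, and 16 genes always. The rule's minimum levels, planned on another scale, were applied to the deposited log2 values as 2 and 0. Of the genes always named, Cxcl1 and Il6 had mean log2 values of 0.34 and 2.64, below the minimum for testing. Responses to TNFa and to BMP4 were compared between backgrounds for genes chosen on the mean of both effects, which is independent of the interaction, at an absolute log2 change of at least 1 for TNFa and 0.5 for BMP4. The correlation of TNFa and BMP4 fold changes, which share the untreated libraries, was set against 50 simulations in which no group differed; these gave an overlap of 0 genes, which is no useful reference for the overlap of calls.

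The procedure was tested on simulated data with 200 changed genes: 90 to 95% of changes of 0.5 log2 were recovered in the pairwise contrasts and 71% in the interaction, with 5 to 11 other genes called. The changes were set on the deposited, compressed scale, with noise independent between genes. The rates therefore do not hold for true changes of this size in weakly expressed genes. HOMER tag totals were 13.7 to 20.6 M tags per library; because the file gives no counts per gene, no counting interval was computed. Alternatives tried were no low-value filter and a minimum of 6, no batch term, a replicate block, batch 2 alone, only the groups compared, quantile normalization, removal of a smooth trend on transcript length from each library (lowess span 0.5), no variance trend, an estimated correlation for the lists, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.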

Results

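RNA was profiled in 12 libraries of MC3T3-E1 mouse osteoblastic cells, 3 each of untreated cells, cells given TNFa (an inflammatory cytokine that activates NF-kB), cells given BMP4 (a bone morphogenetic protein that signals through Smad proteins), and cells given TNFa and then BMP4. By its title the series concerns how Smad4 and the NF-kB subunit p65 (Rela) interact when BMP protects cells against inflammatory death. Tag totals lay between 13.7 and 15.5 M per library, except for 20.6 M in TNFa+BMP4 replicate 2. The first principal component of the 11765 tested genes held 48% of the variance. Between the 2 batches, each of which contains all 4 groups, 7541 genes differed. Values below are log2 fold changes ± SE with n = 3 libraries per group, adjusted for batch, unless another measure is named. Rankings by size are on the deposited log2 scale, which compresses changes of weakly expressed genes, and genes said not to pass are those limma did not call. Positions are mm10.

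The comparison of TNFa with untreated cells gives the response to the cytokine alone. The 6 largest rises on the deposited log2 scale include chemokine, NF-kB inhibitor and interferon-inducible genes. Ccl2, a monocyte chemoattractant (NM_011333, chromosome 11, 82035577 to 82037452), rose by 4.36 ± 0.21, from a level of 5.81 ± 0.09 to 10.16 ± 0.73 (mean log2 ± SD). The complement gene C3 rose by 3.74 ± 0.15, the IkB-family inhibitor Nfkbie (NM_008690, chromosome 17, 45555700 to 45563168) by 3.71 ± 0.05, the interferon-inducible GTPase Gbp2 by 3.28 ± 0.08, the pattern receptor Tlr2 by 2.99 ± 0.11 and the chemokine Ccl7 by 2.75 ± 0.18. The 6 largest decreases were smaller: Mtus1 (-1.08 ± 0.09), Rflnb (-1.04 ± 0.12), Tafa5 (-0.96 ± 0.07), Dhrs3 (-0.90 ± 0.11) and Cyp26b1 (-0.86 ± 0.14), which encode retinoid enzymes, and the growth factor receptor Fgfr2 (-0.82 ± 0.09). For weakly expressed genes these values are compressed: the authors' deposited fold change is 7.81 for Ccl2 and 6.84 for C3.

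Among NF-kB subunits and feedback inhibitors, 13 of 15 rose (14 higher and 0 lower adjusted over the list alone), with Nfkbia (NM_010907, chromosome 12, 55489409 to 55492647) at 2.60 ± 0.13, Tnfaip3 at 2.52 ± 0.11 and Rela at 0.78 ± 0.05. For NF-kB genes camera gave adjusted p = 6.84e-30, and adjusted p = 0.0251 with an estimated correlation. Of the chemokines 7 of 8 rose (7 higher and 0 lower adjusted over the list alone). Another 10 of the 18 fixed chemokines, Cxcl1, Cxcl2 and Cxcl5 among them, were below the minimum level and not tested. For chemokines camera gave adjusted p = 8.44e-14, and adjusted p = 0.0251 with an estimated correlation. In the list of interferon response and antigen presentation 20 of 21 rose (20 higher and 0 lower adjusted over the list alone), Gbp3 among them at 1.93 ± 0.11. For interferon genes camera gave adjusted p = 3.34e-33, and adjusted p = 0.0251 with an estimated correlation. Of the survival factors 6 of 12 rose and 1 fell (8 higher and 1 lower adjusted over the list alone), including the apoptosis inhibitors Birc3 (1.57 ± 0.12) and Birc2 (0.86 ± 0.07). For survival factors camera gave adjusted p = 9.79e-06, and adjusted p = 0.0514 with an estimated correlation. Of the cytokines, prostaglandin enzymes and osteoclast regulators 4 of 6 rose (5 higher and 1 lower adjusted over the list alone), with Csf1, a macrophage growth factor, at 1.98 ± 0.07 and Lif at 1.04 ± 0.10. For these regulators camera gave adjusted p = 3.47e-05, and adjusted p = 0.123 with an estimated correlation. In the adhesion and matrix remodelling list 7 of 13 rose and 4 fell (7 higher and 4 lower adjusted over the list alone), with Vcam1 at 2.29 ± 0.05 and Icam1 at 1.92 ± 0.10, for which the authors' deposited fold change is 7.51. For the adhesion list camera gave adjusted p = 0.00321, and adjusted p = 0.145 with an estimated correlation.

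Cell-death genes moved with TNFa as well. Of the apoptosis genes 7 of 18 rose and 2 fell (7 higher and 3 lower adjusted over the list alone), with the death receptor Fas at 2.27 ± 0.09 and the BH3-only gene Bid at 0.69 ± 0.06. For apoptosis genes camera gave adjusted p = 0.00396, and adjusted p = 0.112 with an estimated correlation. Of the necroptosis and pyroptosis genes 5 of 8 rose (6 higher and 0 lower adjusted over the list alone), with the inflammatory caspase Casp4 at 1.61 ± 0.09, the pore-forming Gsdmd at 1.26 ± 0.09 and Mlkl, which carries out necroptosis, at 0.35 ± 0.07. For necroptosis and pyroptosis camera gave adjusted p = 2.59e-05, and adjusted p = 0.0851 with an estimated correlation. Casp8 rose by 0.21 ± 0.07, a call the authors' deposited analysis does not make, while the values of Ripk1 (0.16 ± 0.06), Ripk3 (0.04 ± 0.08) and Smad4 (-0.03 ± 0.05) did not pass the test. Of the immediate-early genes and MAP kinase phosphatases 9 of 17 rose and 1 fell (11 higher and 2 lower adjusted over the list alone), with Junb at 2.02 ± 0.09 and Fosl1 at 1.34 ± 0.11. For immediate-early genes camera gave adjusted p = 4.34e-06, and adjusted p = 0.133 with an estimated correlation.

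Several BMP and bone genes fell with TNFa. Of the BMP-Smad target genes 2 of 20 rose and 7 fell (2 higher and 7 lower adjusted over the list alone): Id3 (-0.68 ± 0.07), Atoh8 (-0.57 ± 0.17), Smad6 (-0.48 ± 0.10) and Id1 (-0.34 ± 0.08) fell and Smad7 rose by 0.34 ± 0.11. For BMP-Smad targets camera gave adjusted p = 0.00646, and adjusted p = 0.328 with an estimated correlation. Of the osteoblast differentiation and bone matrix genes 1 of 11 rose and 4 fell (1 higher and 5 lower adjusted over the list alone), with the transcription factor Mef2c at -0.78 ± 0.09 and the parathyroid hormone receptor Pth1r at -0.65 ± 0.09. Another 7 of the 18 fixed, Alpl, Bglap, Ibsp and Dmp1 among them, were below the minimum level and not tested. For osteoblast genes camera gave adjusted p = 0.00244, and adjusted p = 0.0872 with an estimated correlation. Of the Wnt pathway genes 3 of 11 fell (0 higher and 5 lower adjusted over the list alone), with Lrp6 at -0.45 ± 0.06 and Tcf7 at -0.42 ± 0.07. For Wnt genes camera gave adjusted p = 3.37e-04, and adjusted p = 0.0386 with an estimated correlation. Of the BMP and TGF-beta ligands, receptors and Smads 3 of 16 rose (3 higher and 0 lower adjusted over the list alone), Smad3 by 0.85 ± 0.05 and Tgfb1 by 0.65 ± 0.11. For ligands and receptors camera gave adjusted p = 0.553, and adjusted p = 0.624 with an estimated correlation; their median was -0.011 and their mean 0.081. In all, limma called 1822 genes, 1078 higher and 744 lower, and 1821 of them had the same direction in both batches. With quantile normalization 963 were higher and 951 lower. Batch 2 alone gave 1734 genes and a model with no batch term 383, while batch 1 has 1 library per group and cannot be tested alone. The calls of Id1, Smad7, Casp8 and Atoh8 held in 4, 3, 1 and 3 of the 6 fits that left out 1 library, with largest adjusted p of 0.0636 and 0.355 without untreated replicate 1 for Id1 and Smad7 and 0.244 and 0.235 without TNFa replicate 1 for Casp8 and Atoh8.

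**Figure D1:**
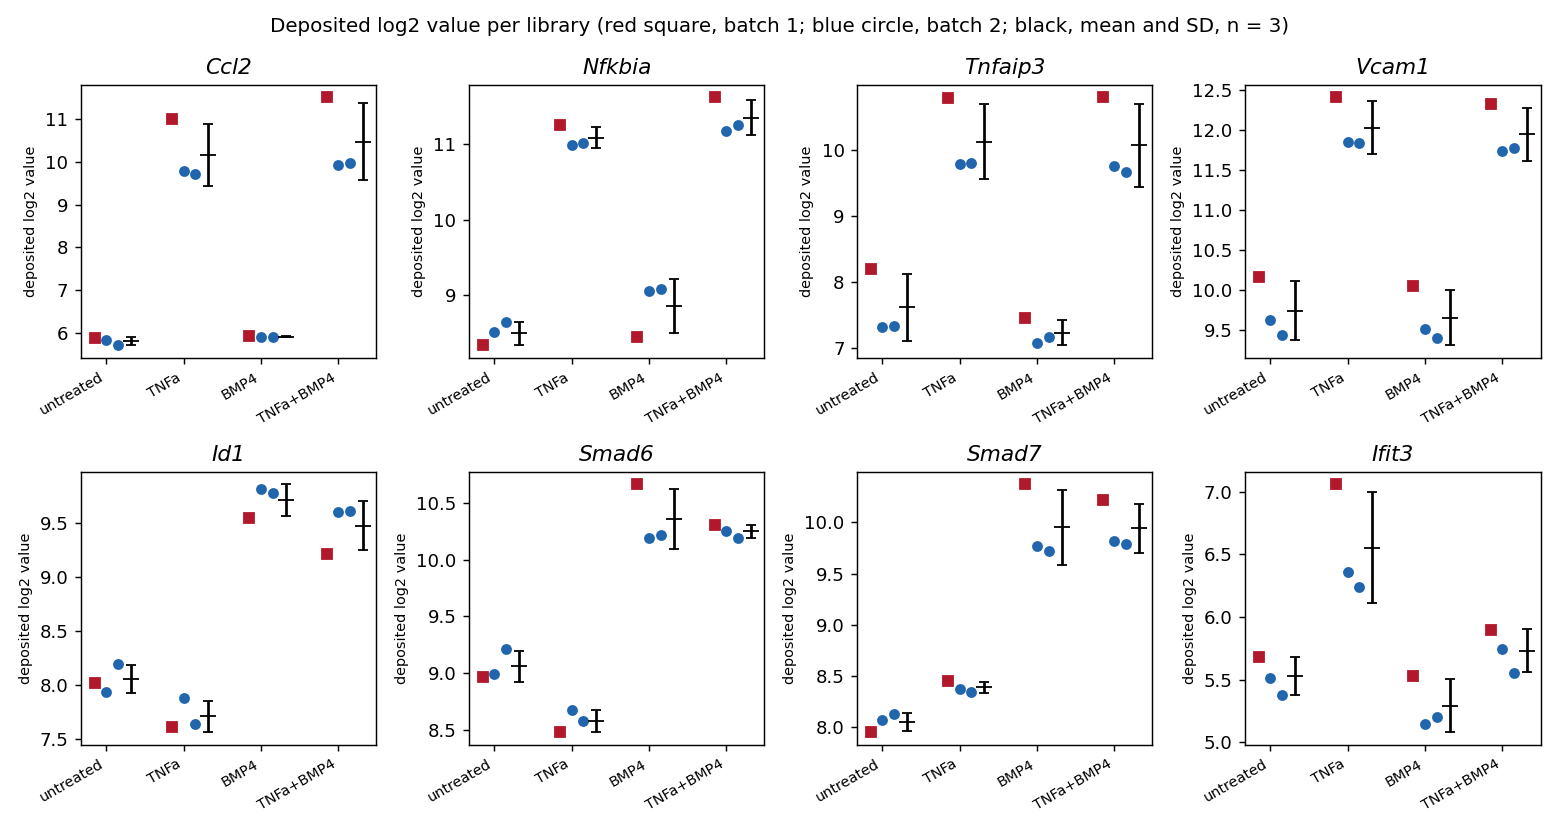
Deposited log2 values of 8 genes in each of the 12 libraries, by group; red squares are batch 1, blue circles batch 2, and black marks the mean and SD of 3 libraries. Ccl2 rose by 4.36 with TNFa and Id1 by 1.66 with BMP4.

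BMP4 alone, compared with untreated cells, raised genes known as targets of BMP-Smad signalling. The inhibitors of differentiation Id1 (NM_001369018, chromosome 2, 152736251 to 152737410) and Id3 rose by 1.66 ± 0.08 and 1.84 ± 0.07, and the inhibitory Smads Smad6 and Smad7 by 1.30 ± 0.10 and 1.90 ± 0.11. The level of Id1 went from 8.05 ± 0.13 to 9.71 ± 0.15 (mean log2 ± SD). Snai1, a transcriptional repressor (2.08 ± 0.08), Atoh8 (1.99 ± 0.17), the stress gene Gadd45b (1.94 ± 0.07) and the keratin Krt16 (1.68 ± 0.13) were among the 6 largest increases. The 6 largest decreases were Mgat3 (-0.87 ± 0.10), Carns1 (-0.86 ± 0.11), Trerf1 (-0.80 ± 0.09), Sft2d2 (-0.79 ± 0.09), Plekha7 (-0.79 ± 0.11) and Bicd1 (-0.75 ± 0.12).

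Among BMP-Smad target genes 14 of 20 rose (14 higher and 0 lower adjusted over the list alone). For BMP-Smad targets camera gave adjusted p = 1e-21, and adjusted p = 0.0251 with an estimated correlation. In the Wnt pathway 5 of 11 rose (6 higher and 1 lower adjusted over the list alone), with Wnt11 at 1.20 ± 0.08 and Lef1 at 0.90 ± 0.10. For Wnt genes camera gave adjusted p = 6.62e-05, and adjusted p = 0.0279 with an estimated correlation. Of the osteoblast genes 2 of 11 rose (3 higher and 0 lower adjusted over the list alone), namely Sp7, a transcription factor needed for bone formation (0.80 ± 0.12), and Pth1r (0.64 ± 0.09). For osteoblast genes camera gave adjusted p = 0.00947, and adjusted p = 0.128 with an estimated correlation. Among chondrocyte markers 2 of 5 rose (2 higher and 0 lower adjusted over the list alone), Col2a1 by 0.65 ± 0.14 and Sox9 by 0.46 ± 0.09. For chondrocyte markers camera gave adjusted p = 0.115, and adjusted p = 0.23 with an estimated correlation. Of the immediate-early genes 9 of 17 rose and 1 fell (9 higher and 3 lower adjusted over the list alone), with Junb at 1.64 ± 0.09 and Fos at 0.75 ± 0.09. For immediate-early genes camera gave adjusted p = 4.83e-05, and adjusted p = 0.165 with an estimated correlation. Of the YAP and TGF-beta-responsive matrix genes 5 of 10 rose and 1 fell (5 higher and 1 lower adjusted over the list alone), with Ccn1 at 1.20 ± 0.09. For these matrix genes camera gave adjusted p = 0.0542, and adjusted p = 0.155 with an estimated correlation. Among survival factors 2 of 12 rose (5 higher and 0 lower adjusted over the list alone), Gadd45b and Ier3 (0.54 ± 0.10). For survival factors camera gave adjusted p = 0.0126, and adjusted p = 0.165 with an estimated correlation.

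Of the apoptosis genes 6 of 18 fell (0 higher and 7 lower adjusted over the list alone), with the BH3-only genes Pmaip1 at -0.52 ± 0.11 and Bid at -0.48 ± 0.06. For apoptosis genes camera gave adjusted p = 0.00363, and adjusted p = 0.11 with an estimated correlation. Without untreated replicate 1, BMP4 replicate 1 or BMP4 replicate 3, 3 apoptosis genes were called lower in each case. Of the chemokines 0 of 8 were called (0 higher and 0 lower adjusted over the list alone). For chemokines camera gave adjusted p = 0.679, and adjusted p = 0.811 with an estimated correlation. Ccl2 had 0.10 ± 0.21 and Cxcl12 0.18 ± 0.09. In the interferon list 3 of 21 fell (0 higher and 3 lower adjusted over the list alone), including Irf1 (-0.52 ± 0.10) and Tap1 (-0.46 ± 0.09). For interferon genes camera gave adjusted p = 0.0118, and adjusted p = 0.404 with an estimated correlation. The NF-kB inhibitor Tnfaip3 fell by 0.39 ± 0.08, and its call held in 3 of the 6 fits that left out 1 library (largest adjusted p = 0.189, without BMP4 replicate 1). Nfkbia (0.37 ± 0.13), Vcam1 (-0.09 ± 0.05), Smad4 (0.04 ± 0.05), Rela (0.01 ± 0.05), Casp8 (-0.09 ± 0.07), Ripk1 (0.06 ± 0.06) and Mlkl (-0.05 ± 0.07) did not pass. In the authors' deposited analysis Nfkbia was called for BMP4 and Tnfaip3 and Col2a1 were not. In all 1438 genes were called, 794 higher and 644 lower, of which 1435 had the same direction in both batches. The larger share turned round with quantile normalization (605 higher and 687 lower), and with no variance trend 597 were higher and 586 lower. A separate fit of batch 2 alone called 1264 genes, 970 of them shared. The count was 114 with no batch term, 756 without untreated replicate 1 and 951 without BMP4 replicate 1.

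**Figure D2:**
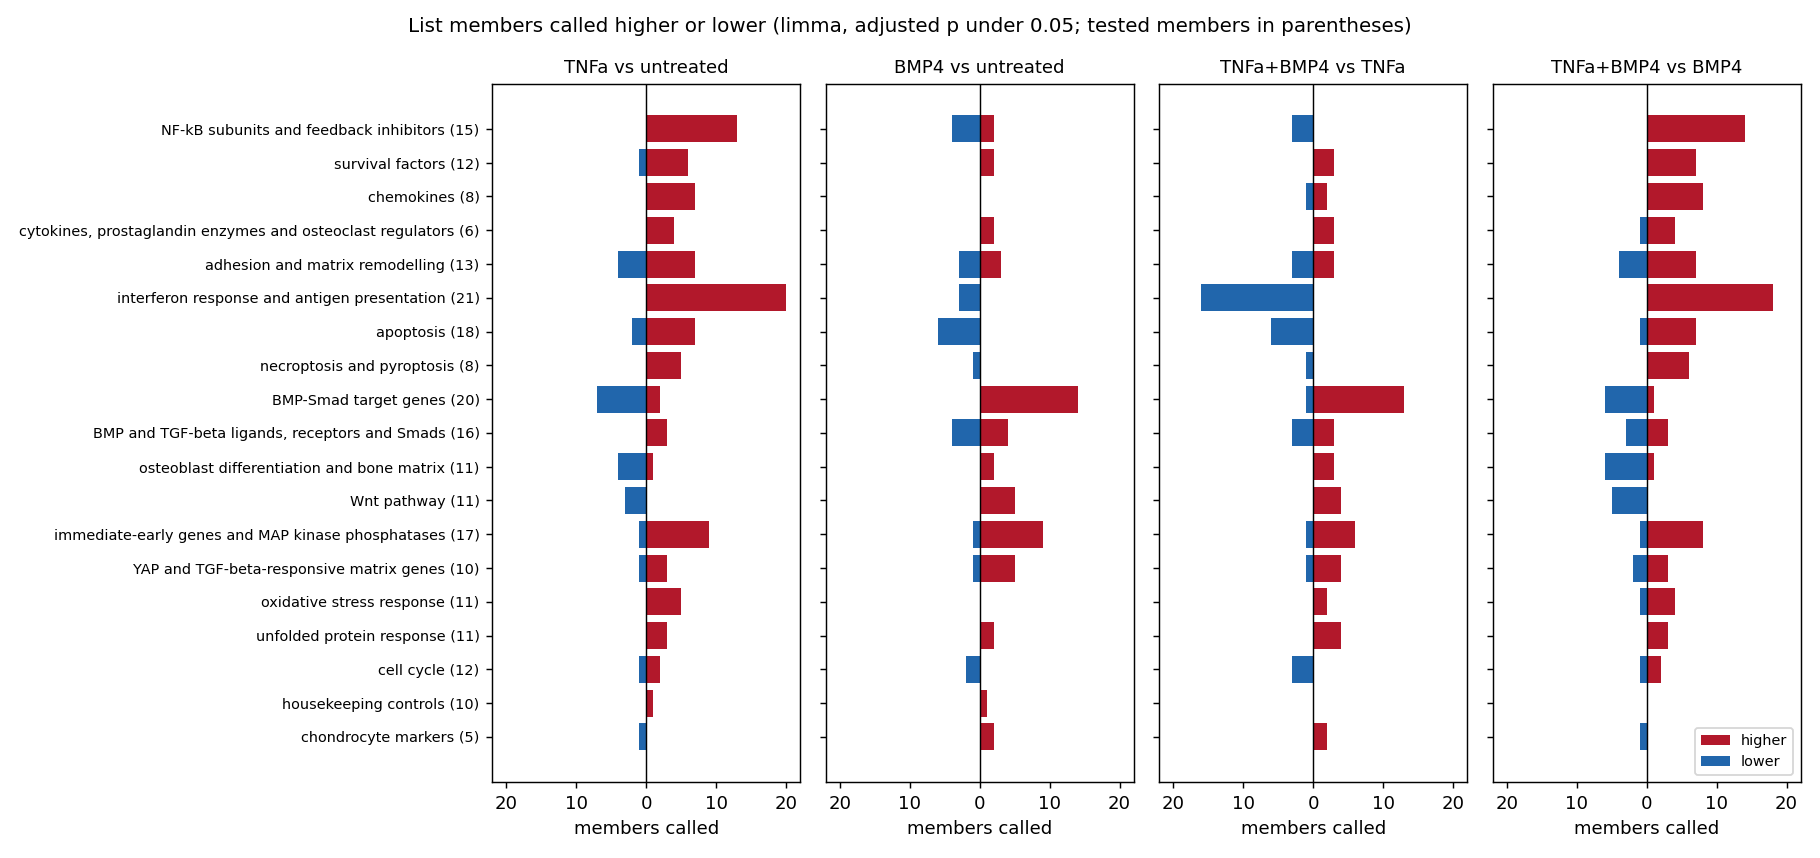
Number of members of each of the 19 tested lists called higher (red, to the right) or lower (blue, to the left) in 4 comparisons, with tested members in parentheses. With TNFa 20 of 21 interferon genes rose, and 16 fell when BMP4 was added to TNFa.

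Cells given both factors were compared with untreated cells to read the combined response. Ccl2 (4.66 ± 0.21), Tlr2 (3.48 ± 0.11), Nfkbie (3.38 ± 0.05) and Ccl7 (3.32 ± 0.18) were again among the 6 largest increases, joined by Junb (3.22 ± 0.09) and Krt16 (3.19 ± 0.13), which each factor raised alone. The BMP-Smad targets Id1 and Smad7 rose by 1.42 ± 0.08 and 1.89 ± 0.11. The 6 largest decreases were the receptor Erbb3 (-1.33 ± 0.12), Carns1 (-1.22 ± 0.11), Faah (-1.17 ± 0.12), Ehbp1 (-1.12 ± 0.06), Mtus1 (-1.10 ± 0.09) and Fam189a2 (-1.08 ± 0.09).

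Among NF-kB genes 13 of 15 rose (13 higher and 0 lower adjusted over the list alone). For NF-kB genes camera gave adjusted p = 6.24e-17, and adjusted p = 0.0514 with an estimated correlation. Among chemokines 8 of 8 rose (8 higher and 0 lower adjusted over the list alone). For chemokines camera gave adjusted p = 1.93e-10, and adjusted p = 0.0251 with an estimated correlation. Among interferon genes 17 of 21 rose (17 higher and 0 lower adjusted over the list alone). For interferon genes camera gave adjusted p = 1.29e-12, and adjusted p = 0.0734 with an estimated correlation. Of the BMP-Smad targets 13 of 20 rose and 1 fell (15 higher and 1 lower adjusted over the list alone). For BMP-Smad targets camera gave adjusted p = 2.5e-09, and adjusted p = 0.0851 with an estimated correlation. In the adhesion and matrix remodelling list 7 of 13 rose and 3 fell (7 higher and 3 lower adjusted over the list alone), with Vcam1 at 2.20 ± 0.05 and Icam1 at 1.78 ± 0.10. For the adhesion list camera gave adjusted p = 0.0222, and adjusted p = 0.23 with an estimated correlation. Of the survival factors 8 of 12 rose (9 higher and 0 lower adjusted over the list alone), with Gadd45b at 1.90 ± 0.07 and Birc3 at 1.46 ± 0.12. For survival factors camera gave adjusted p = 8.02e-07, and adjusted p = 0.0386 with an estimated correlation. Apoptosis genes went both ways, with 5 of 18 higher and 5 lower (5 higher and 5 lower adjusted over the list alone). Their camera test gave adjusted p = 0.479, and adjusted p = 0.624 with an estimated correlation. Necroptosis and pyroptosis genes had 5 of 8 higher and 0 lower (5 higher and 1 lower adjusted over the list alone). Their camera test gave adjusted p = 0.00645, and adjusted p = 0.1915 with an estimated correlation. Among oxidative stress genes 6 of 11 rose and 1 fell (6 higher and 1 lower adjusted over the list alone), with the heme-degrading enzyme Hmox1 at 1.06 ± 0.11 and Srxn1 at 0.68 ± 0.09. For oxidative stress genes camera gave adjusted p = 0.00645, and adjusted p = 0.0872 with an estimated correlation. In the unfolded protein response 6 of 11 rose (6 higher and 0 lower adjusted over the list alone), with Xbp1 at 0.55 ± 0.05 and the chaperone Hspa5 at 0.46 ± 0.06. For the unfolded-protein list camera gave adjusted p = 0.00464, and adjusted p = 0.294 with an estimated correlation. Of the cell cycle genes 1 of 12 rose and 3 fell (1 higher and 3 lower adjusted over the list alone), with Ccnd1 at 0.57 ± 0.06 and the inhibitor Cdkn1b at -0.49 ± 0.06. For cell cycle genes camera gave adjusted p = 0.479, and adjusted p = 0.68 with an estimated correlation. Without TNFa+BMP4 replicate 1, 1 cell cycle gene was lower. Of the housekeeping controls 2 of 10 rose, Actb among them at 0.18 ± 0.05 (2 higher and 0 lower adjusted over the list alone). For housekeeping controls camera gave adjusted p = 0.221, and adjusted p = 0.457 with an estimated correlation. Limma called 3673 genes, 1973 higher and 1700 lower, of which 3662 had the same direction in both batches. With quantile normalization the larger share turned round (1643 higher and 2020 lower). Batch 2 alone gave 2972 and a model with no batch term 869.

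Adding BMP4 to cells already given TNFa is the comparison closest to the title. Atoh8 (2.29 ± 0.17), Id3 (2.27 ± 0.07), Snai1 (1.92 ± 0.08), Id1 (1.76 ± 0.08), Gadd45b (1.75 ± 0.07) and Smad6 (1.67 ± 0.10) were the 6 largest increases on this scale. In the authors' deposited fold changes Lef1 has 3.41 and Sp7 2.37, above the 2.19 of Id1. The 6 largest decreases were Rasgef1a (-1.03 ± 0.08), Trerf1 (-0.90 ± 0.09), Samd9l (-0.90 ± 0.10), C3 (-0.86 ± 0.15), the interferon-induced Ifit3 (-0.82 ± 0.10; NM_010501, chromosome 19, 34583529 to 34588982) and Mgat3 (-0.77 ± 0.10). The level of Ifit3 was 5.53 ± 0.15 in untreated cells, 6.55 ± 0.44 with TNFa and 5.73 ± 0.17 with both (mean log2 ± SD).

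Of the interferon response and antigen presentation genes 16 of 21 fell (0 higher and 17 lower adjusted over the list alone), with Ifit1 at -0.68 ± 0.16. For interferon genes camera gave adjusted p = 6.63e-13, and adjusted p = 0.0734 with an estimated correlation. The 5 members that did not pass, named after their values were seen, were Irf1, Psmb9, B2m, H2-K1 and H2-D1. Batch 2 alone had 10 members lower, and 8 and 9 were lower without TNFa replicate 1 and without TNFa+BMP4 replicate 1. Of the BMP-Smad targets 13 of 20 rose and 1 fell (13 higher and 1 lower adjusted over the list alone). For BMP-Smad targets camera gave adjusted p = 2.11e-21, and adjusted p = 0.0251 with an estimated correlation. In the Wnt pathway 4 of 11 rose (5 higher and 0 lower adjusted over the list alone), with Lef1 at 1.04 ± 0.10 and Wnt11 at 1.03 ± 0.08. For Wnt genes camera gave adjusted p = 0.00126, and adjusted p = 0.0514 with an estimated correlation. Of the cytokines, prostaglandin enzymes and osteoclast regulators 3 of 6 rose (3 higher and 0 lower adjusted over the list alone), with the prostaglandin enzyme Ptgs2 at 0.65 ± 0.09 and Tnfrsf11b, a decoy receptor that restrains osteoclast formation, at 0.61 ± 0.08. For these regulators camera gave adjusted p = 0.013, and adjusted p = 0.294 with an estimated correlation.

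Of the apoptosis genes 6 of 18 fell (1 higher and 8 lower adjusted over the list alone), with Pmaip1 at -0.66 ± 0.11 and Bid at -0.38 ± 0.06. For apoptosis genes camera gave adjusted p = 0.00645, and adjusted p = 0.123 with an estimated correlation. Of the necroptosis and pyroptosis genes 1 of 8, Casp12, fell (-0.31 ± 0.09), with 0 higher and 1 lower adjusted over the list alone. For necroptosis and pyroptosis camera gave adjusted p = 0.206, and adjusted p = 0.491 with an estimated correlation. The Casp12 call held in 2 of the 6 fits that left out 1 library, with the largest adjusted p = 0.135 without TNFa replicate 1. Among survival factors 3 of 12 rose (4 higher and 0 lower adjusted over the list alone), with Ier3 at 0.52 ± 0.10. For survival factors camera gave adjusted p = 0.0667, and adjusted p = 0.292 with an estimated correlation; their median was -0.007 and their mean 0.191. Of the NF-kB genes 3 of 15 fell (0 higher and 4 lower adjusted over the list alone), including Nfkbie (-0.33 ± 0.05) and Cyld (-0.32 ± 0.05). For NF-kB genes camera gave adjusted p = 0.0222, and adjusted p = 0.45 with an estimated correlation. Values that did not pass were those of Smad4 (-0.05 ± 0.05), Rela (-0.05 ± 0.05), Casp8 (-0.17 ± 0.07), Ripk1 (0.10 ± 0.06), Ripk3 (-0.06 ± 0.08), Mlkl (-0.04 ± 0.07), Birc3 (-0.12 ± 0.12), Ccl2 (0.31 ± 0.21), Vcam1 (-0.08 ± 0.05) and Tnfaip3 (-0.05 ± 0.11); the authors' deposited analysis calls Ccl2 higher. The call of Ifit1 was lost without TNFa replicate 1 (adjusted p = 0.106). In all 1373 genes were called, 643 higher and 730 lower, of which 1372 had the same direction in both batches. A separate fit of batch 2 alone called 1264 genes, 991 of them shared, and there the larger share turned round (644 higher and 620 lower), as with no batch term (66 and 39). The count was 105 with no batch term, 906 with no low-value filter, 2096 with only these groups in the model, 752 without TNFa replicate 1, 800 without TNFa+BMP4 replicate 1 and 909 without TNFa replicate 2.

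**Figure D3:**
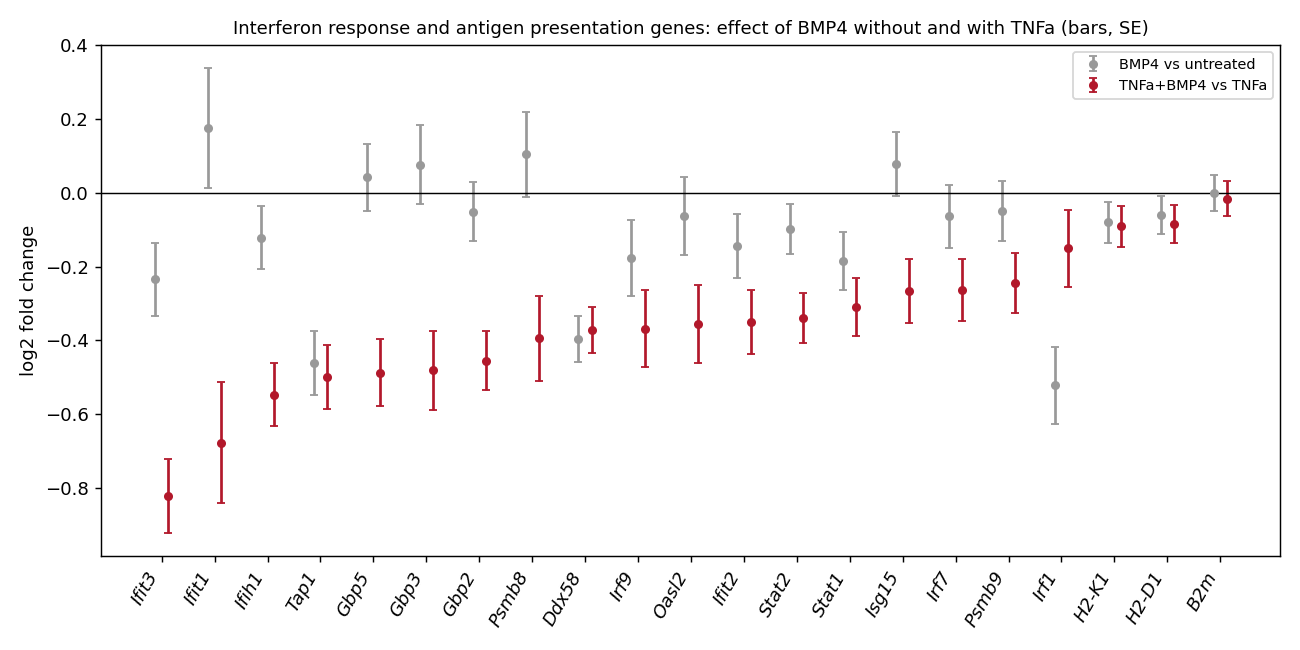
Log2 fold change and SE of the 21 tested interferon and antigen presentation genes for BMP4 against untreated (grey) and TNFa+BMP4 against TNFa (red). With TNFa present 16 members fell, Ifit3 by the most at -0.82, and without it 3 fell. The median difference of the 2 effects was -0.205. That difference was called for 0 of the 21 members, and camera with an estimated correlation gave adjusted p = 0.0872 for the list. Without TNFa replicate 1, 8 members were called lower with TNFa present.

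The effect of TNFa in cells also given BMP4 was read from TNFa+BMP4 against BMP4 alone. Ccl2 (4.56 ± 0.21), Tlr2 (3.40 ± 0.11), Nfkbie (3.22 ± 0.05), Ccl7 (3.17 ± 0.18), Gbp2 (2.87 ± 0.08) and Tnfaip3 (2.85 ± 0.11) were the 6 largest increases. The 6 largest decreases were Mtus1 (-1.21 ± 0.09), Mef2c (-1.06 ± 0.09), Cyp26b1 (-1.05 ± 0.14), Rflnb (-1.04 ± 0.12), Fam180a (-1.01 ± 0.11) and Erbb3. Of the NF-kB genes 14 of 15 rose (14 higher and 0 lower adjusted over the list alone). For NF-kB genes camera gave adjusted p = 4.98e-30, and adjusted p = 0.0251 with an estimated correlation. Of the chemokines 8 of 8 rose (8 higher and 0 lower adjusted over the list alone). For chemokines camera gave adjusted p = 2.43e-14, and adjusted p = 0.0251 with an estimated correlation. Of the interferon genes 18 of 21 rose (18 higher and 0 lower adjusted over the list alone), with Irf1 at 1.65 ± 0.10. For interferon genes camera gave adjusted p = 1.49e-23, and adjusted p = 0.0276 with an estimated correlation. Among apoptosis genes 7 of 18 rose and 1 fell (8 higher and 2 lower adjusted over the list alone), with Fas at 2.10 ± 0.09 and Bid at 0.79 ± 0.06. For apoptosis genes camera gave adjusted p = 0.00175, and adjusted p = 0.0872 with an estimated correlation. Among necroptosis and pyroptosis genes 6 of 8 rose (6 higher and 0 lower adjusted over the list alone), with Casp4 at 1.30 ± 0.09, Gsdmd at 1.23 ± 0.09 and Mlkl at 0.35 ± 0.07. For necroptosis and pyroptosis camera gave adjusted p = 1.54e-05, and adjusted p = 0.0815 with an estimated correlation. Of the osteoblast genes 1 of 11 rose and 6 fell (2 higher and 7 lower adjusted over the list alone), with Pth1r at -0.68 ± 0.09. For osteoblast genes camera gave adjusted p = 5.08e-04, and adjusted p = 0.0734 with an estimated correlation. Of the Wnt genes 5 of 11 fell (0 higher and 7 lower adjusted over the list alone), with Wnt4 at -0.61 ± 0.11 and Lrp6 at -0.54 ± 0.06. For Wnt genes camera gave adjusted p = 2.59e-05, and adjusted p = 0.0251 with an estimated correlation. Smad6 (-0.11 ± 0.10), Smad7 (-0.01 ± 0.11) and Id1 (-0.24 ± 0.08) did not pass, though the authors' deposited analysis calls Id1 lower. Limma called 1905 genes, 1033 higher and 872 lower, of which 1902 had the same direction in both batches. With quantile normalization the larger share turned round (939 higher and 1024 lower). A separate fit of batch 2 alone called 1797 genes, 1459 of them shared, and a model with no batch term 345.

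Whether BMP4 altered the response to TNFa was tested by the interaction, in which 2 genes passed. Nfkbie, raised by TNFa in both backgrounds, had an interaction of -0.49 ± 0.07 (adjusted p = 0.02), so its TNFa response was smaller with BMP4. Pdgfb, a growth factor gene (NM_011057, chromosome 15, 79995865 to 80014977), had 1.02 ± 0.17 (adjusted p = 0.0382). Pdgfb did not pass with the replicate block (adjusted p = 0.117), quantile normalization (adjusted p = 0.0828), no variance trend (adjusted p = 0.0995) or no low-value filter (adjusted p = 0.342), nor did Nfkbie with no low-value filter (adjusted p = 0.056), and neither passed with no batch term. At an unadjusted p under 0.05, 560 genes passed. Both calls changed with the libraries used: leaving out 1 library gave 0 to 7 genes, with Nfkbie called in 5 of 12 such fits and Pdgfb in 4, and largest adjusted p of 0.113 without TNFa replicate 1 and 0.189 without untreated replicate 2. Batch 2 alone gave 15 genes, 9 with an interaction above 0 and 6 below. Among those above were the BMP-Smad targets Id3 (0.42), Atoh8 (0.49) and Smad6 (0.49), and among those below C3 (-0.88). None of these passed in the full fit, and their batch 1 values were 0.44, -0.06, 0.13 and -1.04. Interactions that did not pass included those of Smad4 (-0.09 ± 0.08), Rela (-0.06 ± 0.08), Casp8 (-0.08 ± 0.10), Ripk1 (0.04 ± 0.08), Ripk3 (0.00 ± 0.11), Mlkl (0.01 ± 0.10), Birc3 (-0.09 ± 0.16), Ccl2 (0.21 ± 0.30) and Vcam1 (0.00 ± 0.08).

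As a list, the interferon genes had a median interaction of -0.205, with Ifit1 at -0.85 ± 0.23 and Ifit3 at -0.59 ± 0.14. The interaction was below 0 for 19 of 21 members. Irf1 went the other way (0.37), with a TNFa effect of 1.27 without BMP4 and 1.65 with it. In this list 0 of 21 members were called over all genes by limma and 1 higher and 9 lower adjusted over the list alone. For interferon genes camera gave adjusted p = 1.93e-10, and adjusted p = 0.0872 with an estimated correlation. Limma's fry gave adjusted p = 0.0431 for a joint direction, adjusted over the 114 list tests. Apoptosis genes had a median of -0.01 and a mean of -0.002, with the camera direction up. For apoptosis genes camera gave adjusted p = 0.829, and adjusted p = 0.888 with an estimated correlation. BMP-Smad targets had a median of 0.031, with 0.079 in batch 2 and -0.046 in batch 1. For BMP-Smad targets camera gave adjusted p = 0.187, and adjusted p = 0.624 with an estimated correlation. In these lists 0 members were called over all genes by limma. Adjusted over the list alone, 0 apoptosis genes and 1 BMP-Smad target, higher, were called. Of the NF-kB genes 1 of 15, Nfkbie, had a called interaction, below 0 (0 higher and 3 lower adjusted over the list alone), with a median of -0.06 for the list. For NF-kB genes camera gave adjusted p = 0.0429, and adjusted p = 0.491 with an estimated correlation. Of the immediate-early genes 0 of 17 were called (0 higher and 2 lower adjusted over the list alone), with a median of -0.055. For immediate-early genes camera gave adjusted p = 0.0464, and adjusted p = 0.45 with an estimated correlation.

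Over the wider response, 89 genes had a mean TNFa effect of at least 1 log2 in size, 87 raised and 2 lowered, and 57 of them (64%) had a smaller effect with BMP4. Their median interaction was -0.10. Limma's fry gave adjusted p = 0.153 for a joint direction and adjusted p = 0.0549 for change in either direction, adjusted over the 2 responses. The joint direction passed fry's unadjusted test in batch 2 alone (median -0.14), without BMP4 replicate 1 (-0.123) and without TNFa+BMP4 replicate 1 (-0.137). Of 194 genes with a mean BMP4 effect of at least 0.5, 137 raised and 57 lowered, 100 (51.5%) had a smaller effect with TNFa. Their median interaction was -0.003 (fry adjusted p = 0.984), and 0.015 in batch 2 alone. Across all tested genes, which are not independent replicates, the TNFa effects with and without BMP4 had r = 0.885 and slope 0.857, and the BMP4 effects with and without TNFa r = 0.788 and slope 0.791. Noise in the fold changes lowers such slopes, so they do not measure a smaller response. For the 89 and 194 chosen genes the slopes were 0.909 and 0.986. Of the genes called, 1252 were called in the same direction for TNFa in both backgrounds and 0 in opposite directions. For BMP4 these numbers were 798 and 2.

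**Figure D4:**
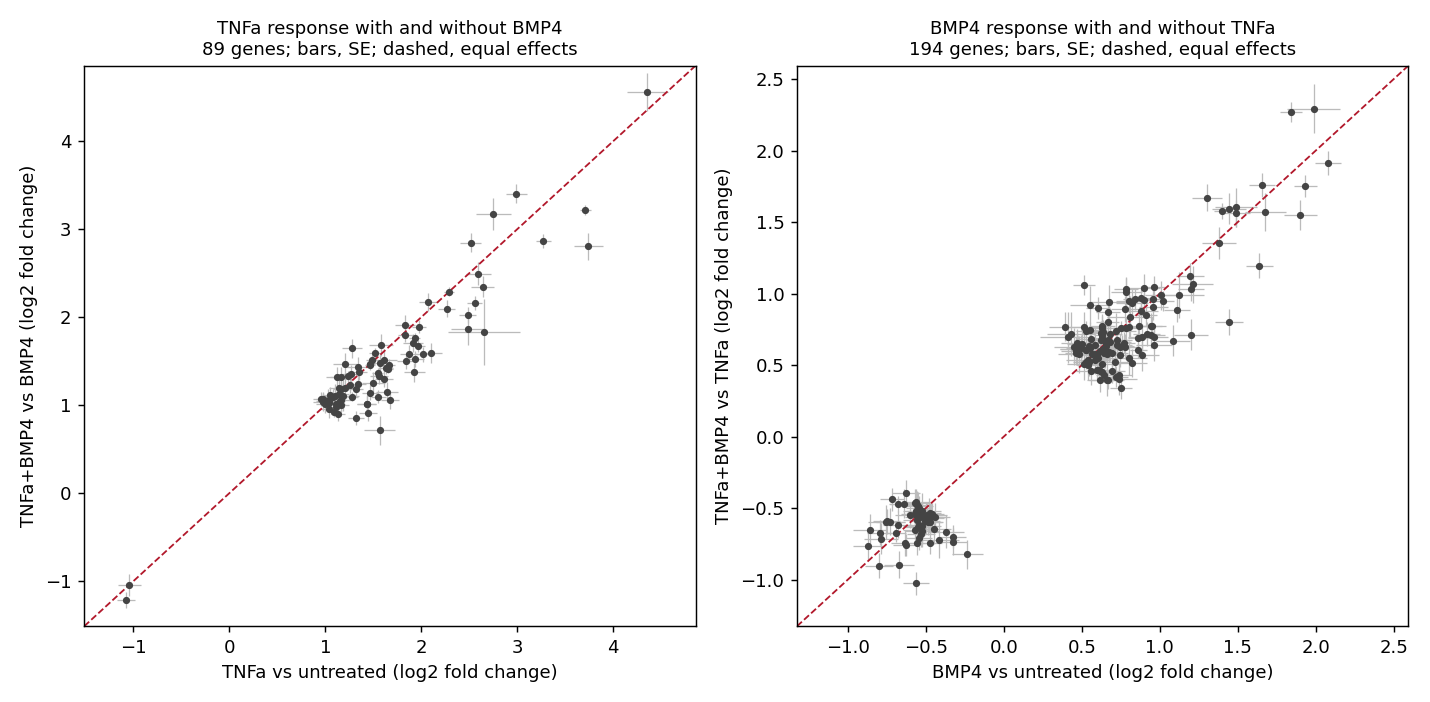
Effect of TNFa with BMP4 against its effect without (left, 89 genes) and of BMP4 with TNFa against its effect without (right, 194 genes), in log2 fold change with SE; the dashed line marks equal effects. Of these genes 57 and 100 have the smaller effect when the other factor is present.

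TNFa and BMP4 calls against the shared untreated libraries overlapped in 504 genes. In this set 140 rose with both, including Junb (2.02 with TNFa, 1.64 with BMP4), and 163 fell with both. Another 82 rose with TNFa and fell with BMP4, including Tnfaip3 (2.52 and -0.39), and 119 fell with TNFa and rose with BMP4, including Id3 (-0.68 and 1.84) and Pth1r (-0.65 and 0.64). Independent lists would give 72.75, 40.73, 59.01 and 50.21, numbers that do not allow for the shared untreated libraries. Across genes, which are not independent replicates, the fold changes had r = 0.0978 and a covariance of 0.00406. Simulations with no group difference, where the shared libraries alone produce correlation, gave a mean r of 0.499 and a mean covariance of 0.00313. Group effects enlarge the variances in the data and not in the simulations, so the r values cannot be set against each other. The covariance, which is not divided by these variances, was higher in the data. Genes with large changes in the same direction, Junb and Krt16 among them, weigh most in a covariance. It therefore does not show how many genes respond to both factors. The overlap was 14 with no batch term, 297 with no low-value filter, 461 in batch 2 alone and 245 without untreated replicate 1.

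The deposited analysis by the authors called 1535, 859, 2499, 1239 and 1439 of the tested genes for the 5 pairs in the order described. Of these, 1458, 842, 2487, 1077 and 1398 were also called here, 0 with the opposite direction.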

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

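The tests of the larger TNFa and BMP4 effects in batch 1, of the interferon list in each batch and of the residual spread of relabellings, and the rule that left the single-library count of interferon genes undecided, were set after the results were seen, as were the counts of genes that differ between batches. The interaction test singled out 2 genes whose TNFa response differed with BMP4: Nfkbie, with -0.49, and Pdgfb, with 1.02. Of 100 relabellings of BMP4 within the TNFa strata, the real one included, 4 gave as many genes, but these counts do not show whether chance can be excluded. The other 99 each had a larger residual SD (median 0.0981 against 0.0839), since the BMP4 effect entered it, which can lower their counts. The highest other relabelling gave 12, several times the real 2; it kept the real BMP4 groups without TNFa and mixed them with TNFa, so the BMP4 effect itself entered its interaction.

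The interferon list had a median interaction of -0.205, lower with both factors than the single effects add up to, and 16 of its 21 members fell when BMP4 was added to TNFa. A trend on transcript length is argued against: with the trend removed 17 members were called lower and the median interaction was -0.225. The authors' fold changes gave a median interaction of -0.269 (95% bootstrap interval over members -0.606 to -0.027). This argues against compression of low values as the source of the median, for these libraries. Bootstrap intervals over members treat them as independent and leave out the spread between libraries. A single library as the cause of the fall with BMP4 after TNFa is argued against: 21 of 21 members were lower in batch 1 (median -0.52) and 20 of 21 in batch 2 (median -0.277, 95% bootstrap interval over members -0.332 to -0.195), which share no library. How many members are called stays open, with 8 without TNFa replicate 1, at the bound set beforehand, and 10 in batch 2 alone. The interaction itself was below 0 for 15 of 21 members in batch 1 (median -0.396) and 17 in batch 2 (median -0.176). Irf1 had an interaction above 0 in the full fit, at 0.37. A smaller interferon response in the presence of BMP4 may be biological, but the list test has adjusted p = 0.0872 with an estimated correlation, so this remains a hypothesis.

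A test of batch against treatment found 503 genes whose TNFa effect differed between batches and 710 whose BMP4 effect did; batch 1 has 1 library per group, so the spread in this test came from the batch 2 pairs alone. Of the 87 genes raised by TNFa, 69 had a larger effect in batch 1 for TNFa against untreated and 59 (67.8%) for TNFa+BMP4 against BMP4, pairs that share no library, which argues against 1 odd library as the whole cause; of the 137 genes raised by BMP4, 116 (84.7%) against untreated and 99 (72.3%) against TNFa were larger as well, so the pattern is not particular to TNFa. A uniform stretch of the log2 scale in batch 1 stays open: 8 genes raised by TNFa and 2 raised by BMP4 had a called smaller effect there, but without replicates in batch 1 such calls exclude nothing. For the same reason a difference in exposure, culture or sequencing between batches could not be tested apart. No biological explanation was tested for this pattern.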

How the results depend on the processing

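Alternatives chosen after the data were seen are the minimum of 6, quantile normalization, the length trend, no variance trend, the left-out libraries for lists and named genes, and every alternative for the overlap. Those planned before the data were examined that need counts (another normalization, other count models, a count filter, a prior count) were not run, because the file holds no counts. With no batch term the counts in the order described were 383, 114, 869, 105, 345 and 0 and the overlap 14, since batch differences then enter the spread. With no low-value filter TNFa+BMP4 against TNFa gave 906, the interaction 0 and the overlap 297. TNFa+BMP4 against TNFa gave 2096 with only its groups in the model. The interaction gave 1 gene with the replicate block, 1 with quantile normalization and 15 in batch 2 alone. Of the calls of named genes 101 were lost with no batch term and 8 in batch 2 alone, where 12 were gained. Of the list tests 13 passed with an estimated correlation. In batch 2 alone the TNFa response had a median of -0.14 and the BMP4 response reversed to 0.015. Over the fits that leave out 1 library the ranges were 1297 to 1662 (TNFa), 756 to 1332 (BMP4; 756 without untreated replicate 1, 951 without BMP4 replicate 1), 2560 to 3380 (both), 752 to 1066 (both against TNFa; 752 without TNFa replicate 1, 800 without TNFa+BMP4 replicate 1, 909 without TNFa replicate 2), 1320 to 1594 (both against BMP4), 0 to 7 (interaction; 7 without BMP4 replicate 1, and 0 or 1 without untreated replicate 1, 2 or 3, TNFa replicate 1, 2 or 3, BMP4 replicate 2, and TNFa+BMP4 replicate 2 or 3), -0.139 to -0.062 (TNFa response), -0.04 to 0.063 (BMP4 response; above 0 without untreated replicate 1, BMP4 replicate 1, TNFa replicates 2 and 3 and TNFa+BMP4 replicates 2 and 3), 57 to 62 (list tests) and 245 to 448 (overlap; 245 without untreated replicate 1). Among named genes not called, signs reversed in batch 2 alone for Birc3 (0.037), Smad4 (-0.023), Rela (-0.061) and Mlkl (0.035) with BMP4, Ripk3 (0.023) with both, Mlkl (0.011) for both against TNFa, Smad6 (0.014) and Smad7 (0.061) for both against BMP4, and for the interactions of Ptges (-0.068), Gsdme (-0.028), Vcam1 (-0.0042), Rela (0.0105), Ripk3 (-0.067) and Mlkl (-0.024). They also reversed with quantile normalization for Birc3 (0.014), Smad4 (-0.015) and Rela (-0.047) with BMP4, and with the length trend removed for Smad7 (0.0063) for both against BMP4 and the interactions of Ripk3 (-0.018) and Mlkl (-0.012). The cause of these shifts was not tested. Low levels limit the fold changes, whose compression eases with level, from a slope of 0.26 at a mean log2 of 4 to 6 to 0.92 above 10.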

Other observations

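The tests of the gene groups and of the batch difference were chosen after the values were seen. Camera p-values of groups chosen in this way are no independent support for them. Tests of the length trend and of other splits were set before their results. The exceptions are the 16 library choices and the rule that left the single-batch test of the length trend undecided.

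With TNFa the immunoproteasome, which cuts proteins into peptides for antigen presentation, rose as a group: 5 of 5 rose. For the immunoproteasome camera gave adjusted p = 1.46e-09, and adjusted p = 0.0491 with an estimated correlation. Of the antigen presentation genes named H2-, 9 of 13 rose. For H2- genes camera gave adjusted p = 7.61e-08, and adjusted p = 0.0522 with an estimated correlation. Among pattern-recognition receptors 6 of 9 rose. For pattern-recognition receptors camera gave adjusted p = 9.8e-09, and adjusted p = 0.0491 with an estimated correlation. They include Tlr2 at 2.99 ± 0.11, Nod2 at 1.83 ± 0.10 and Nod1 at 1.13 ± 0.07. The group also holds Ripk2 (1.55 ± 0.07), which is a kinase and not itself a receptor. Of the complement genes 3 of 5 rose. For complement genes camera gave adjusted p = 1.65e-04, and adjusted p = 0.0904 with an estimated correlation. Their median interaction was -0.242. For complement genes camera gave adjusted p = 1.58e-04, and adjusted p = 0.0904 with an estimated correlation. Among retinoid enzymes and receptors 4 of 6 fell. For the retinoid group camera gave adjusted p = 0.00129, and adjusted p = 0.134 with an estimated correlation. Those called lower include Cyp26b1 (-0.86 ± 0.14), Dhrs3 (-0.90 ± 0.11), Rara (-0.21 ± 0.06) and Rarg (-0.20 ± 0.06). Among translation initiation factors, with both factors against untreated cells, 26 of 54 rose and 1 fell. For initiation factors camera gave adjusted p = 1.03e-05, and adjusted p = 0.0879 with an estimated correlation. Of the proteasome subunits 21 of 38 rose in that comparison. For proteasome subunits camera gave adjusted p = 3.89e-07, and adjusted p = 0.134 with an estimated correlation. Of the cytosolic ribosomal protein genes 1 of 92 rose and 2 fell with TNFa. For ribosomal protein genes camera gave adjusted p = 0.284, and adjusted p = 0.83 with an estimated correlation. In the interaction limma called 0 of 92, with a median of 0.045. For ribosomal protein genes camera gave adjusted p = 1.03e-05, and adjusted p = 0.372 with an estimated correlation. These transcripts are short (median 732 bases), and with the length trend removed the median was -0.007 (camera adjusted p = 0.782). Of the respiratory chain genes 1 of 82 rose with both factors. For respiratory chain genes camera gave adjusted p = 0.362, and adjusted p = 0.767 with an estimated correlation. In the interaction limma called 0 of 82, with a median of 0.068. For respiratory chain genes camera gave adjusted p = 5.18e-06, and adjusted p = 0.134 with an estimated correlation. With both factors against TNFa their median was 0.063. For respiratory chain genes camera gave adjusted p = 0.00372, and adjusted p = 0.316 with an estimated correlation. These transcripts are short too (median 741 bases), and with the length trend removed the medians were 0.016 and 0.031 (camera adjusted p = 0.241 and 0.184). The tested genes in the shortest 10% had a median interaction of 0.048. Of the cholesterol synthesis genes 4 of 17 rose and 1 fell with BMP4. For cholesterol synthesis camera gave adjusted p = 0.199, and adjusted p = 0.704 with an estimated correlation.

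The pre-ribosomal RNA Rn45s, a sign of RNA composition looked at after its values were seen, was called lower with TNFa and with BMP4 (-0.55 and -0.53) and is 1 of the 504 genes called in both. In batch 2 its log2 value was 12.91 and 12.88 in the untreated libraries and 11.94 to 12.26 in the other 6. In batch 1, with 1 library per group, it was 14.46 untreated, 14.26 with TNFa, 14.72 with BMP4 and 14.24 with both. The fall with BMP4 alone was thus not seen in batch 1. Rn45s and Lars2 are 2 of the 15 interaction calls in batch 2 alone, which also include Id3, Atoh8, Smad6 and C3. Without untreated replicate 2 or 3 the overlap of calls was 448 or 416; leaving out both was not tested.

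Between batches, with group in the model, 7541 of the 11765 tested genes differed, 3774 higher in batch 1 and 3767 lower. The nuclear RNAs Neat1 and Malat1 were higher in batch 1 by 3.96 and 3.09 log2, and the matrix genes Fmod and Postn by 3.58 and 3.21. Lower in batch 1 were Arrdc4 (-1.88), Txnip (-1.58), Bmp4 (-1.58) and the mitotic genes Plk1 (-1.50) and Cenpa (-1.45). List tests between batches are given with the preset correlation only, and no value with an estimated correlation is given. Of the YAP and TGF-beta-responsive matrix genes 10 of 10 were higher in batch 1 (camera adjusted p = 2.21e-07), of the unfolded protein response genes 8 of 11 were higher and 1 lower (camera adjusted p = 0.0222), and of the cell cycle genes 7 of 12 were lower and 3 higher (camera adjusted p = 0.0222).

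Across genes the interaction fell with transcript length, with a Spearman rho of -0.312; genes are not independent replicates. A single library as its cause is argued against, since the rho nearest 0 over the 12 fits that leave out 1 library was -0.171, without BMP4 replicate 1. Whether it rests on 1 batch cannot be told apart: rho was -0.35 in batch 1 and -0.122 in batch 2, but over 16 choices of 1 library per group in batch 2 it ran from -0.16 to 0.01, with 8 below -0.1. No biological explanation was tested.

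For each pair of groups the 6 libraries make 10 splits, so no share under 0.1 can be had. In each of the 5 comparisons 1 split, the real one, gave as many genes. The counts were 1822, 1438, 3673, 1373 and 1905, and the highest of the other splits gave 0. Each other split mixes libraries of both groups, so the treatment effect enters its spread, which can lower its count. These counts therefore do not show whether chance can be excluded.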
